A study of Danio rerio with 12 samples.

How the data were processed

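Messenger RNA was measured in pools of 100 larval zebrafish tails, wild type per the labels, in 12 libraries that form 4 groups of 3. The groups were cut or uncut tails, each with the vehicle dimethyl sulfoxide (DMSO) or with SB431542. Per the labels' protocols, tissue was dissociated in TRI Reagent, RNA was purified further by lithium chloride precipitation, and libraries were made with the Lexogen QuantSeq FWD kit. That kit primes on the poly(A) tail and reads the end of each transcript next to it, so a count stands for transcripts of a gene whatever their length, and differences in splicing or in upstream exons are not seen. The labels do not say that the samples of a group came from separate clutches or matings, beyond each being a pool of 100 tails, so the p-values measure the spread between these pools, which may be partly technical.

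The authors deposited a table of estimated counts for 30258 Ensembl genes, not normalized, in which 23.1% to 26.7% of the values above 0 in a library were not whole. The genome build was GRCz11 per the submitters' processing notes, and the aligner and the counting program are not given in the sources used here. Fractional counts arise where reads that match several genes are shared between them, so values of near-identical copies are less certain than those of single genes. The authors also deposited a normalized table, a signal per gene that is scaled by 1 factor per library. Multiplying each of its values by that factor returned a whole number of reads, within 1e-04, for 100% of values, and 100% of these equalled the rounded estimated counts of the deposited count table. Total counts ran from 7368986 to 12914981 per library.

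Gene symbols came from a table of gene IDs and symbols, which matched 23598 of the 30258 IDs (77.99%). Symbols are printed as that table gives them, letter case included, and 3440 genes share their symbol with another ID. The Ensembl ID is printed at first mention of the genes described in full and of any named gene with a shared symbol. No genome or annotation was used here, so no coordinates are given.

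The estimated counts were rounded to whole numbers and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with trimmed-mean scaling (TMM), the filter filterByExpr, robust dispersion estimates and 1 fit of the 4 group means, which left 13978 genes tested. The common biological coefficient of variation was 0.261. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with calls at an adjusted p under 0.05. Every adjusted p of a gene is from this edgeR test unless another tool is named. Levels are CPM, counts scaled to a common library size with the TMM factors, given as mean ± SD over 3 libraries, and log2 fold changes are given ± SE. The comparisons were cut against uncut tails under DMSO, the same under SB431542, SB431542 against DMSO in cut and in uncut tails, and the interaction of excision and SB431542.

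33 lists of pathways and cell types were written before the data were examined. Of their entries, 354 matched a symbol exactly, 289 with letter case ignored and 232 without a closing paralogue letter, which takes in every ID of that symbol, and 61 matched none. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. Every adjusted p of a list is from the preset correlation unless it is named as estimated. A list is said to have moved by its test against all other genes, so single members can move the other way.

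Genes to be named were also set by a rule written before the data were examined. They were the 12 largest increases and the 12 largest decreases among called genes with a mean of at least 5 CPM, a symbol that is not a clone or placeholder name, and no overlap between the 3 libraries of each group, plus up to 4 members of a described list with the smallest adjusted p. Placeholder prefixes such as CR and FO were applied only where digits followed, a departure from the rule as written that keeps genes such as FOSL2. In addition, 6 genes known to respond to TGF-β signalling were fixed for every comparison, of which 1 is not reported here.

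Alternatives set before the data were examined were median-of-ratios (RLE) and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no count filter, a stricter filter of 10 counts in every library of a group and a mean of 1 CPM, limma-trend on the deposited normalized table with a pseudocount of 1 or 0.1, the replicate number as a block, a fit of only the 2 groups compared, and leaving out each library in turn. For the lists, fry was also run. Added after the data were seen were the test on reads recovered from the normalized table, limma-voom with library weights, leave-outs of 1 library for the lists and the correlations, the leave-out of uncut SB431542 replicate 4 where it is in neither group compared, and a contrast that averages SB431542 over cut and uncut tails. No 2 libraries of a group agreed within sampling noise, since the smallest chi-square per gene was 8.28.

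The tests were run on simulated data with gene means taken over all 12 libraries, their library sizes and the fitted dispersion trend. Known changes were put into the cut DMSO libraries, and cut and uncut tails under DMSO were compared. Among 13754 genes, edgeR recovered 6% of genes changed 1.5-fold, 36% of those changed 2-fold, 86% of those changed 4-fold and 91.8% of those changed 8-fold, and 10 of its 119 calls were unchanged genes. A simulated shift of the cell cycle list was called with an adjusted p of 1.75e-22 and 0 of the 32 other lists were called. Genes were drawn independently of each other, so this does not test the lists where members are correlated, as in real tissue.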

Results

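Gene expression was measured in tails of zebrafish larvae after tail excision, with and without SB431542, an inhibitor of the type I receptors ALK4, ALK5 and ALK7 through which TGF-β, activin and nodal ligands signal. In the cut groups about 200 µm of the tail was removed at the pigment gap at 72 h post fertilization, and 18 h later a further 200 µm was collected for RNA. In the uncut groups the same region was collected at 90 h from larvae that had not been operated on. SB431542 was given at 50 µM from 72 to 90 h, and 0.1% DMSO served as vehicle. Each of the 4 groups had 3 libraries, and total counts ran from 7368986 to 12914981.

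The cut DMSO libraries lay apart from the uncut DMSO libraries on both leading principal components of log2 CPM, which held 23.7% and 20.3% of the variance. 1 library, uncut SB431542 replicate 4, lay at 49.8 on the first component and 68.3 on the second, while the other libraries of its group lay at -5.84 and -27.3 on the first. Its median correlation with the other libraries was 0.905, against 0.934 to 0.944 for the other 11. Its cell cycle genes lay a median of 1.05 log2 units above the mean of the other libraries of its group, and its erythrocyte genes 1.19 above it. The largest deviations in size of any other library were -0.546 and -0.716, in replicates 3 and 2 of the same group. Each of these was measured against a mean that includes replicate 4. Outside this group the largest were 0.488 and 0.636, both in cut SB431542 replicate 4. The gene zgc:158463, chosen after its values were seen, held 0.267% of its counts against 1.18% to 5.22% in the other 11. The library was kept in every comparison.

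**Figure D1:**
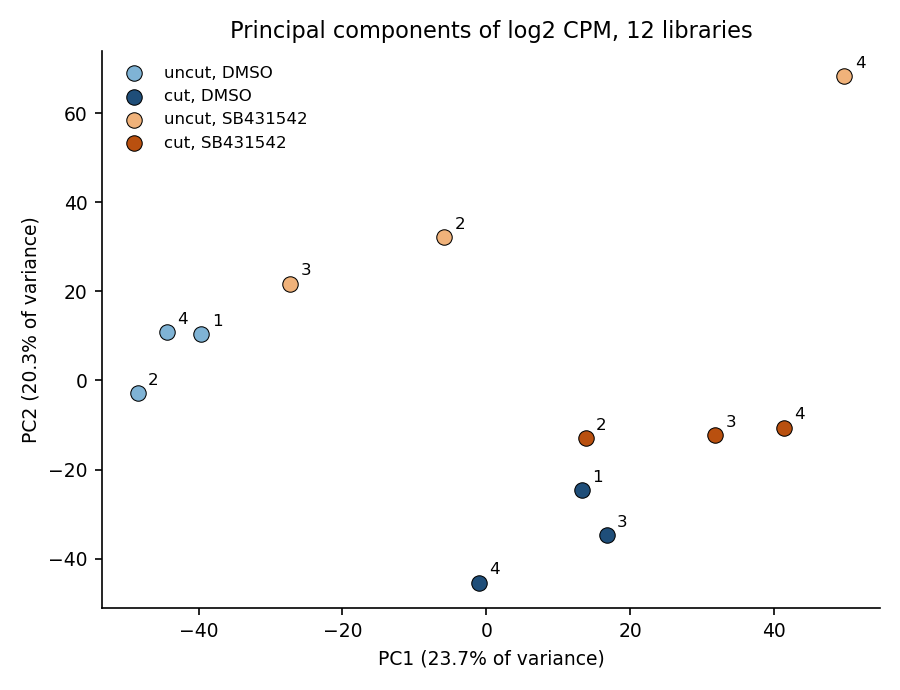
Each point is 1 of the 12 libraries, placed by its first and second principal components of log2 CPM, with 23.7% and 20.3% of the variance on the axes. Uncut SB431542 replicate 4 lies at 49.8 and 68.3, away from the other 2 libraries of its group.

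Cut against uncut tails under DMSO asked how the tail responds to excision. At 18 h, 510 genes were higher and 270 lower in cut tails, 362 and 113 of them by at least 2-fold. The largest increase among the named genes was in the complement gene c4b (ENSDARG00000038424), which rose from 0.590 ± 0.524 to 27.9 ± 0.523 CPM, a log2 fold change of 5.59 ± 0.41 (adjusted p = 4.11e-08). FN1 (ENSDARG00000006526), a fibronectin gene, rose from 14.4 ± 7.08 to 476 ± 228 CPM, or 32.3-fold (log2 fold change 5.01 ± 0.44, adjusted p = 3.78e-05). TIMP2 (ENSDARG00000075261), an inhibitor of matrix metalloproteinases, rose 16.2-fold from 18.7 ± 3.11 to 305 ± 47.0 CPM (adjusted p = 8.89e-10). The gelatinase gene MMP9 (ENSDARG00000042816) rose 10.3-fold from 1.35 ± 0.501 to 14.2 ± 3.90 CPM (adjusted p = 3.57e-05). CARTPT (ENSDARG00000035852), a neuropeptide precursor gene, rose 18.7-fold, and the granulin gene grna.1 rose from a mean of 2.14 to 35.3 CPM (adjusted p = 3.45e-07). Other increases were 11.9-fold for the cathepsin gene ctsl.1, 9.67-fold and 9.55-fold for the olfactomedin genes olfm4l2 and olmf4l1, 9.60-fold for ms4a17a.4 and 9.51-fold for fgfbp2b.

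The largest decrease among the named genes was in the tyrosine catabolism gene hpda, by 5.72-fold at an adjusted p of 0.0480. The actin gene acte1 (ENSDARG00000079111) fell 4.62-fold from 242 ± 34.5 to 52.5 ± 11.2 CPM (adjusted p = 5.08e-06), and col7a1 (ENSDARG00000021720), whose collagen anchors the epidermis to the matrix under it, fell 4.54-fold (adjusted p = 0.000396). The matrix genes epyc, COL11A2, COL2A1 (ENSDARG00000069093) and COL11A1 were lower, by log2 fold changes of -1.87, -1.73, -1.63 and -1.57. The muscle genes XIRP2 (ENSDARG00000071113), ANKRD1 (ENSDARG00000075263), tnni1c and PFKM (ENSDARG00000060797) had log2 fold changes of -2.01, -1.85, -1.65 and -1.58. The gene map1lc3cl was lower by 3.38-fold.

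**Figure D2:**
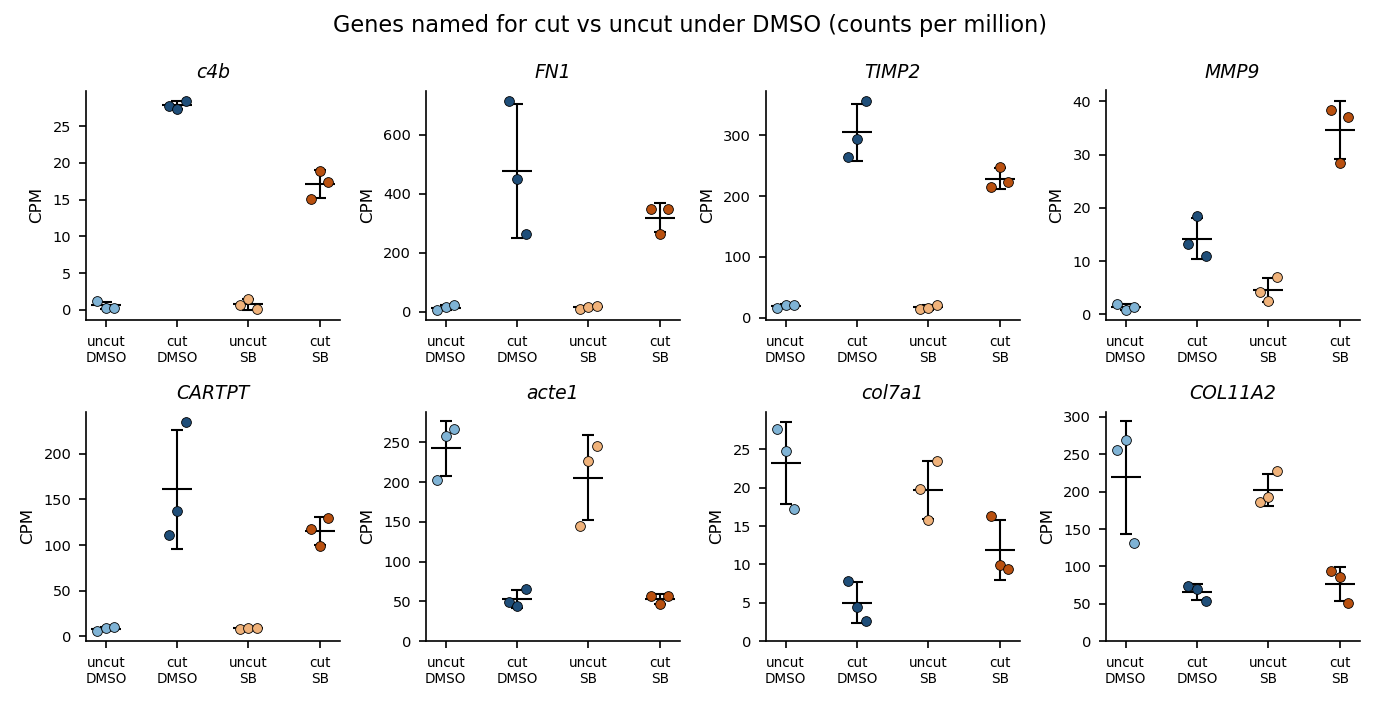
Dashes give the mean CPM of 8 genes in the 4 groups, error bars the SD and points the 3 libraries of each group. FN1 stands at 14.4 and 476 CPM in uncut and cut tails with DMSO, and at 14.9 and 320 CPM with SB431542.

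Leukocyte genes rose together after excision. Of 24 measured macrophage markers, 13 rose and 0 fell (19 and 0 adjusted over the list alone), and the list was higher at an adjusted p of 3.99e-14. The lipid carrier apoeb rose 3.84-fold from 416 ± 102 to 1597 ± 65.2 CPM, the actin-bundling gene LCP1 4.46-fold, the receptor gene havcr1 5.28-fold and the transcription factor gene SPI1 3.63-fold. Of 17 neutrophil markers, 9 rose and 0 fell (9 and 0 adjusted over the list alone, list adjusted p = 4.30e-07), among them adam8a 6.53-fold, the NADPH oxidase subunit gene cyba 3.44-fold, srgn 2.66-fold and npsn 2.44-fold. Cytokine and acute inflammation genes gave 8 increases and 0 decreases among 23 (10 and 0 adjusted over the list alone, list adjusted p = 1.33e-06). SOCS3 (ENSDARG00000026611), a feedback inhibitor of cytokine signalling, rose 6.42-fold from 5.01 ± 1.52 to 32.9 ± 10.4 CPM and the collagenase gene mmp13a 7.51-fold. Of 21 proteases of matrix turnover and their inhibitors, 11 rose and 0 fell (11 and 2 adjusted over the list alone, list adjusted p = 6.81e-08), with TIMP2, adam8a and MMP9 among the increases. Of 29 genes of the wound epidermis and blastema of regenerating fins, 7 rose and 0 fell (10 and 0 adjusted over the list alone, list adjusted p = 1.33e-06), including the AP-1 gene JUNB (ENSDARG00000074378) from 6.44 ± 1.89 to 33.4 ± 7.31 CPM and the vault protein gene MVP at 4.85-fold. TIMP2, MMP9 and mmp13a are members of more than 1 of these lists. With an estimated correlation the adjusted p was 0.0259 for macrophages, 0.0397 for neutrophils, 0.0135 for cytokines, 0.0135 for proteases and 0.0132 for fin regeneration.

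Muscle and neural genes were lower as groups. Of 34 skeletal muscle genes, 14 fell and 0 rose (25 and 0 adjusted over the list alone, list adjusted p = 2.31e-15, 0.0259 with an estimated correlation). ACTA1 (ENSDARG00000036371) fell 2.82-fold from 1343 ± 261 to 476 ± 47.4 CPM, PGAM2 2.77-fold, CASQ1 (ENSDARG00000038716) 2.07-fold and the parvalbumin gene pvalb1 2.01-fold. Without uncut SB431542 replicate 4, which is in neither group, 21 muscle genes were called and the list had an adjusted p of 0.0568 with an estimated correlation. Of 36 genes of neurons and glia, 5 fell and 0 rose (11 and 0 adjusted over the list alone, list adjusted p = 8.56e-07, 0.0286 with an estimated correlation), among them nefmb at 1.98-fold, GAD1 (ENSDARG00000027419) at 1.78-fold, the myelin gene mbpa at 1.61-fold and CPLX2 at 1.61-fold. Without that library 10 neural genes were called. Of 27 contractile and actin cytoskeleton genes of non-muscle cells and smooth muscle, 9 rose and 0 fell (12 and 1 adjusted over the list alone, list adjusted p = 9.19e-05, 0.0135 with an estimated correlation), with TAGLN (ENSDARG00000045408) up 3.94-fold, LMNA 3.52-fold, CAPG (ENSDARG00000099672) 2.43-fold and actb1 1.73-fold.

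Another 6 lists passed the test with the preset correlation and not with an estimated one. Of 56 cell cycle genes, 14 rose and 0 fell (27 and 0 adjusted over the list alone, list adjusted p = 2.60e-14, adjusted p = 0.229 with an estimated correlation), with the mitotic genes KIF23 up 4.21-fold, cdca8 3.01-fold, plk1 3.00-fold and NCAPG 2.81-fold. Of 29 protein folding and endoplasmic reticulum stress genes, 8 rose and 0 fell (13 and 1 adjusted over the list alone, list adjusted p = 2.58e-05, adjusted p = 0.0936 with an estimated correlation), with MANF up 3.25-fold, PDIA4 3.23-fold, HSP90B1 2.02-fold and calr3a 1.62-fold. There were 27 increases in cell cycle genes and 13 in protein folding genes without uncut SB431542 replicate 4. Of 29 notochord genes, 10 fell and 5 rose (12 and 6 adjusted over the list alone, list adjusted p = 0.00632, adjusted p = 0.228 with an estimated correlation). Among the decreases were epyc, COL11A1 and COL9A2, the last by 2.47-fold, while TAGLN rose as given above. Of 23 genes of the periderm and superficial epidermis, 6 fell and 4 rose (8 and 4 adjusted over the list alone, list adjusted p = 0.0263, adjusted p = 0.295 with an estimated correlation), with the keratins krt17 and krt4 down 2.15- and 2.03-fold and krt18a.1 and krt18b up 5.09- and 1.92-fold.

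The remaining pair of lists concerned TGF-β itself. Of 19 target and feedback genes of TGF-β and activin, 3 rose and 0 fell (3 and 0 adjusted over the list alone, list adjusted p = 0.0263, adjusted p = 0.250 with an estimated correlation). Among these were TIMP2 and THBS1 (ENSDARG00000103775), the latter 2.01-fold. Of 15 ligands, receptors and Smads, tgfb1a alone rose, 1.98-fold from 20.3 ± 5.72 to 39.7 ± 2.46 CPM (adjusted p = 0.00865). The list was higher (1 and 0 adjusted over the list alone, list adjusted p = 0.0300, adjusted p = 0.228 with an estimated correlation). Without uncut SB431542 replicate 4 the list of ligands, receptors and Smads had an adjusted p of 0.0504.

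No call was made for the other 19 lists. Their adjusted p under DMSO was 0.0770 for the aryl hydrocarbon and oxidative stress response, 0.0770 for the circadian clock, 0.0878 for the interferon response, 0.154 for basal epidermis, 0.263 for pigment cells, 0.353 for basement membrane, 0.353 for FGF and ERK, 0.438 for bone and cartilage, 0.443 for immediate early genes, 0.451 for BMP, 0.451 for endothelium, 0.523 for Wnt, 0.587 for hedgehog, 0.716 for collagens, 0.716 for actinotrichia and fin fold mesenchyme, 0.793 for retinoic acid, 0.906 for erythrocytes, 0.908 for hypoxia and glycolysis and 0.954 for ionocytes and mucous cells. Of the 780 genes, 777 were also called without uncut SB431542 replicate 4, when 836 genes were higher and 596 lower. Leaving out 1 of the 6 libraries compared gave 321 to 638 calls, and 22 of the 24 leading genes passed in each of these 6 fits, the exceptions being hpda and COL2A1.

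Cut against uncut tails under SB431542 asked how the tail responds to excision when the receptors are inhibited. Here 208 genes were higher and 80 lower in cut tails, 169 and 42 of them by at least 2-fold. The leading increases were again c4b, at 0.723 ± 0.699 and 17.2 ± 1.92 CPM (log2 fold change 4.72 ± 0.42, adjusted p = 1.43e-06), FN1, 21.4-fold from 14.9 ± 4.81 to 320 ± 49.8 CPM (adjusted p = 0.000168), TIMP2, 13.4-fold from 17.0 ± 3.87 to 229 ± 16.8 CPM (adjusted p = 3.14e-09), and CARTPT, from 8.88 ± 0.741 to 115 ± 15.6 CPM. MFAP4 (ENSDARG00000090783), one of 8 gene IDs with that symbol and a macrophage marker in zebrafish, rose 8.98-fold, MMP9 7.25-fold and the small GTPase gene RRAD 6.83-fold. The largest decreases were map1lc3cl by 4.50-fold, the transglutaminase gene TGM2 (ENSDARG00000070157) by 4.48-fold, acte1 by 3.89-fold and the cartilage gene UCMA by 3.48-fold, followed by PALMD, col9a3, SNCG (ENSDARG00000034423), notum2, chad, COL9A2, COL11A2 and MATN3 (ENSDARG00000069265) by 3.09- to 2.59-fold.

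Of the 8 groups that held with an estimated correlation under DMSO, 6 held here too, all but neutrophils and neural genes. Macrophage markers gave 12 increases and 0 decreases among 24 (14 and 0 adjusted over the list alone, list adjusted p = 9.69e-12, 0.0443 with an estimated correlation), with apoeb up 2.21-fold. Cytokine genes gave 6 and 0 among 23 (11 and 0 adjusted over the list alone, list adjusted p = 9.36e-09, 0.00926 with an estimated correlation), with SOCS3 up 3.43-fold. Proteases of matrix turnover gave 6 and 0 among 21 (10 and 0 adjusted over the list alone, list adjusted p = 5.58e-07, 0.0277 with an estimated correlation). Fin regeneration genes gave 7 and 0 among 29 (9 and 1 adjusted over the list alone, list adjusted p = 5.45e-05, 0.0182 with an estimated correlation), with MVP up 4.98-fold and mmp13a 6.34-fold. Contractile genes gave 5 and 0 among 27 (10 and 0 adjusted over the list alone, list adjusted p = 0.000890, 0.0299 with an estimated correlation), with LMNA up 3.31-fold, TAGLN 2.93-fold and actb1 2.05-fold. Of the muscle genes 5 fell and 0 rose (22 and 0 adjusted over the list alone, list adjusted p = 1.06e-12, 0.0458 with an estimated correlation), with ACTA1 down 2.26-fold. Without uncut SB431542 replicate 4 the muscle list had an adjusted p of 0.0980 with an estimated correlation, and the list of neurons and glia one of 0.0370.

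Further lists passed only with the preset correlation. Cell cycle genes were higher (5 up, 0 down; 22 and 0 adjusted over the list alone; list adjusted p = 1.67e-13, adjusted p = 0.242 with an estimated correlation), with TPX2 up 2.32-fold. Protein folding was higher too (3 up, 0 down; 9 and 1 adjusted over the list alone; list adjusted p = 2.24e-05, adjusted p = 0.0945 with an estimated correlation), with HSP90B1 up 1.87-fold. With uncut SB431542 replicate 4 left out, 24 cell cycle genes rose (42 adjusted over the list alone), and 5 protein folding genes. Neurons and glia were lower with 0 genes called (6 down adjusted over the list alone, list adjusted p = 6.87e-05, adjusted p = 0.0765 with an estimated correlation). Neutrophil markers were higher with 2 called (3 adjusted over the list alone, list adjusted p = 0.000123, adjusted p = 0.117 with an estimated correlation), adam8a at a log2 fold change of 2.03 and srgn at 1.05. Without that library 3 neural genes fell, and 8 neutrophil markers were higher adjusted over the list alone. Notochord genes were lower with 7 down and 3 up (13 and 4 adjusted over the list alone, list adjusted p = 0.000562, adjusted p = 0.133 with an estimated correlation), led by COL9A2 at 2.66-fold, MATN3 at 2.59-fold, col9a1b and epyc, and without that library 8 fell and 5 rose among the 31 tested. Bone and cartilage genes were lower with UCMA called (4 down adjusted over the list alone, list adjusted p = 0.0382, adjusted p = 0.221 with an estimated correlation). Interferon genes were higher with 0 of 7 called (0 adjusted over the list alone, list adjusted p = 0.0438, adjusted p = 0.173 with an estimated correlation). Without uncut SB431542 replicate 4 these last lists had adjusted p-values of 0.210 and 0.316, and 1 of 13 bone and cartilage genes was lower adjusted over the list alone. The other 20 lists were not called, the lowest adjusted p being 0.0571 for immediate early genes, which was 0.00438 without that library (adjusted p = 0.0976 with an estimated correlation).

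Of the 288 genes, 215 were also called without uncut SB431542 replicate 4, when 273 were higher and 126 lower. Leaving out 1 of the 6 libraries gave 119 calls, without cut SB431542 replicate 3, to 399 calls, and 22 of the 24 leading genes passed in each of these fits, the exceptions being fgfbp2b and notum2. Calls fell to 135 without cut SB431542 replicate 4 and to 179 without uncut SB431542 replicate 3.

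**Figure D3:**
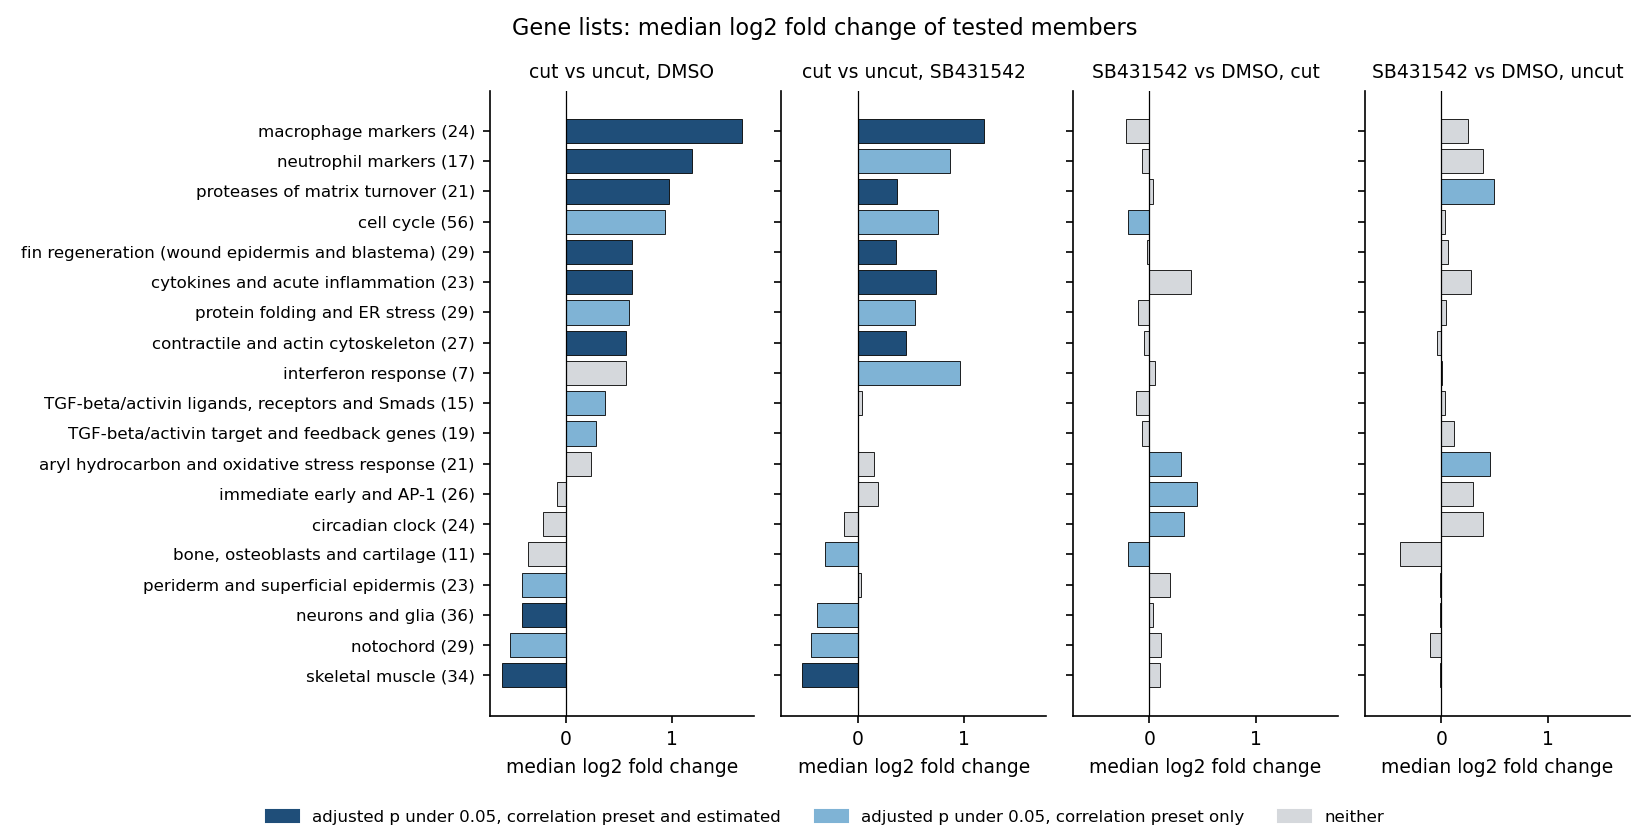
The median log2 fold change of the members of each gene list called in at least 1 of the 4 comparisons is drawn, with lists on the vertical axis and the log2 fold change on the horizontal axis. Macrophage markers lie at 1.65 for excision under DMSO and 1.19 under SB431542, and skeletal muscle at -0.60 and -0.52.

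Across the 13978 tested genes, the log2 fold changes of excision under DMSO and under SB431542 had a Pearson correlation of 0.429 and a Spearman correlation of 0.406, over genes, which are not independent replicates. The comparisons share no library. 153 genes were higher in both and 55 lower in both, where independent lists would share 7.59 and 1.55, and 0 genes were called in opposite directions. Of the 780 genes called under DMSO, 758 had the same sign under SB431542, and the median ratio of their log2 fold changes, SB431542 to DMSO, was 0.659. Among the 288 genes called under SB431542 the median ratio of DMSO to SB431542 was 0.976, and 0.998 at a mean CPM of at least 5. Smaller values in the other comparison were thus seen for the genes called under DMSO, and hardly for those called under SB431542. Each set was chosen by its calls in 1 comparison, so the ratios do not test a difference between treatments.

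**Figure D4:**
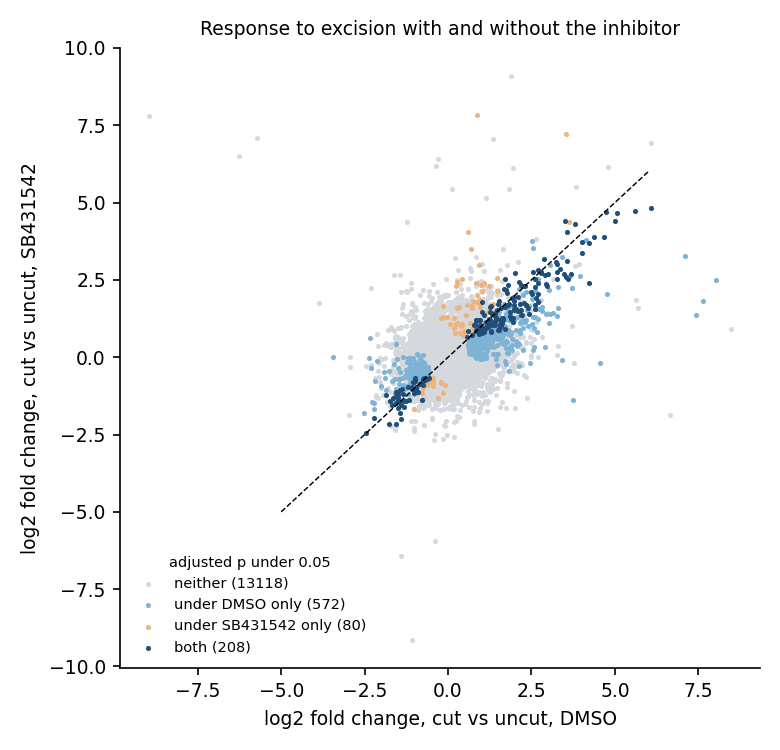
Each point is a gene, with its log2 fold change of cut against uncut tails under DMSO on the horizontal axis and under SB431542 on the vertical axis, and the dashed line marks equal values. 208 genes were called in both, 572 under DMSO only, 80 under SB431542 only and 13118 in neither.

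The interaction of excision and SB431542 tests whether these responses differ. With edgeR 0 genes passed, with 706 at an unadjusted p under 0.05 and a smallest adjusted p of 0.910. DESeq2 gave 0 with 727 at an unadjusted p under 0.05, and limma-voom 0 with 670. None of the 33 lists passed, the lowest adjusted p being 0.0939 for basal epidermis (adjusted p = 0.749 with an estimated correlation), which was 0.0198 without uncut SB431542 replicate 4 (adjusted p = 0.767 with an estimated correlation). Genes called under 1 treatment and not under the other are therefore not shown to differ between treatments. In the simulated comparison of cut and uncut tails, which has a smaller error than an interaction, edgeR recovered 36% of 2-fold changes.

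SB431542 against DMSO in cut tails asked what the inhibitor changes in the tail after excision. In these tails 25 genes were higher and 15 lower with SB431542. The largest decreases were in snorc (ENSDARG00000092383), a proteoglycan gene of cartilage, which was 5.09-fold lower (log2 fold change -2.35 ± 0.31, adjusted p = 0.00215), and in SP6 (ENSDARG00000099880), an epithelial transcription factor gene, 4.55-fold lower at 4.28 ± 1.81 against 19.2 ± 0.115 CPM (adjusted p = 0.00262). PCOLCE2 (ENSDARG00000055575), an enhancer of procollagen processing, and loxl5b (ENSDARG00000076904), of the lysyl oxidase family that crosslinks collagen, were both 3.75-fold lower, and the keratin gene krt97 was 3.32-fold lower at 71.1 ± 5.28 against 236 ± 67.6 CPM. The others were hpcal4 at 2.96-fold, C1QTNF5 at 2.48-fold, FSTL1 (ENSDARG00000015559) at 2.00-fold and cmpk at 1.90-fold lower.

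Among the genes that were higher with SB431542 in cut tails, UCP2 (ENSDARG00000043154), a mitochondrial uncoupling protein gene, was 3.47-fold higher at 131 ± 23.5 against 37.6 ± 14.6 CPM (log2 fold change 1.80 ± 0.24, adjusted p = 0.00212). NR4A1 (ENSDARG00000000796), an immediate early nuclear receptor gene, was 3.43-fold higher (adjusted p = 0.0271), the ammonium transporter gene RHCG (ENSDARG00000007080) 3.34-fold and the mitochondrial membrane gene tspo 2.89-fold. MMP9 was 2.43-fold higher at 34.6 ± 5.48 against 14.2 ± 3.90 CPM (adjusted p = 0.0343), and mmp30, tdh, COX15, RGCC, NAXE, mala.2 and mcrip2 were 2.41- to 2.62-fold higher.

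Of the 9 decreases named, 7 were in genes that had risen on excision under DMSO. The rise was 2.57 ± 0.33 on the log2 scale for SP6, 1.96 ± 0.26 for C1QTNF5, 1.92 ± 0.30 for snorc, 1.67 ± 0.29 for loxl5b, 1.54 ± 0.19 for cmpk, 1.46 ± 0.29 for hpcal4 and 1.43 ± 0.27 for krt97. Under SB431542 the excision response of the same genes was 0.94 ± 0.44 for SP6, 0.22 ± 0.35 for snorc, 0.41 ± 0.35 for loxl5b, -0.24 ± 0.32 for hpcal4 and 0.11 ± 0.27 for krt97, none of which was called, while C1QTNF5 and cmpk were called at 1.27 ± 0.30 and 1.08 ± 0.19. Both comparisons use the cut DMSO libraries, so a high value in these libraries moves both, and such an overlap can arise without any effect of SB431542. The interaction had an adjusted p of 0.910 for each of the 7.

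**Figure D5:**
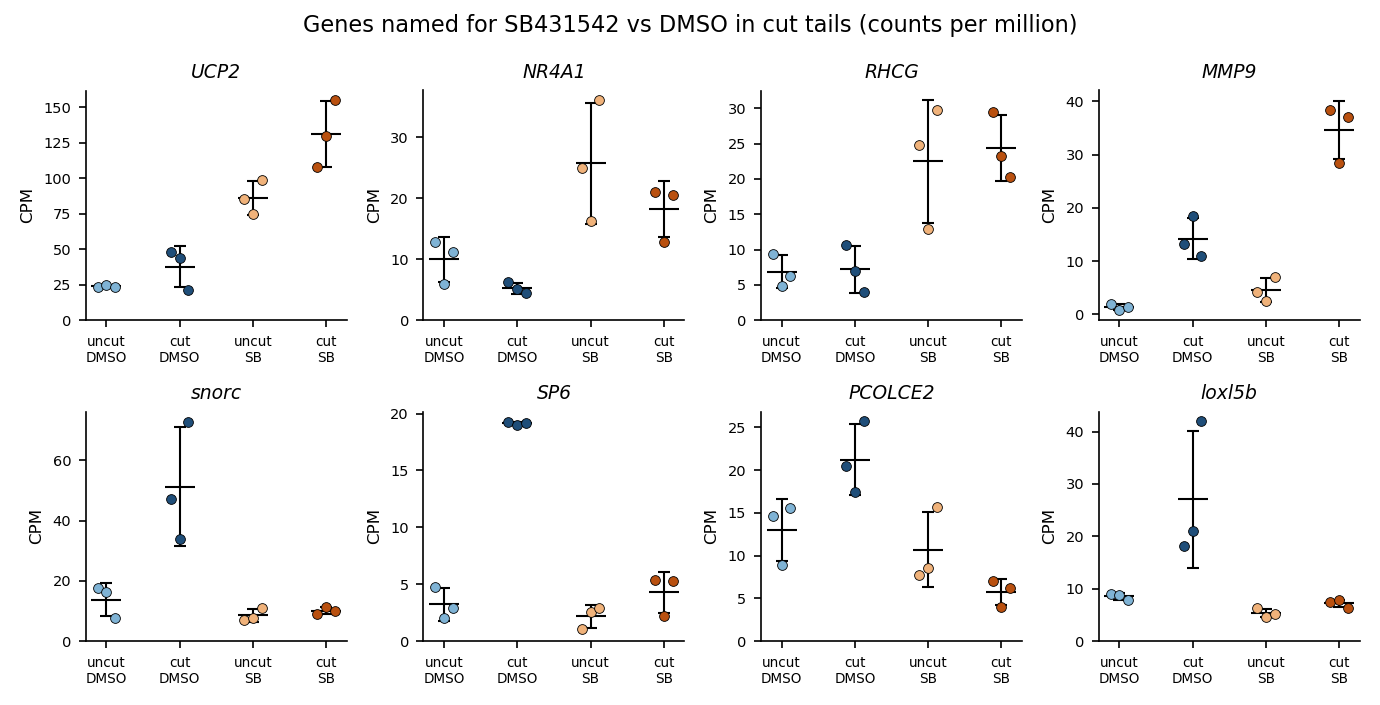
Dashes give the mean CPM of 8 genes called for SB431542 in cut tails, in the 4 groups, with SD as error bars and the 3 libraries of each group as points. SP6 stands at 19.2 CPM in cut tails with DMSO and at 4.28 CPM in cut tails with SB431542.

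As groups, cell cycle genes were lower with SB431542 in cut tails, with 0 of 56 called (0 up and 1 down adjusted over the list alone, list adjusted p = 0.0287, adjusted p = 0.837 with an estimated correlation). Their members went both ways, with UHRF1 at -0.99 ± 0.24 and CENPF at 0.89 ± 0.30 on the log2 scale. Bone and cartilage genes were lower (2 of 11 called, 4 adjusted over the list alone, list adjusted p = 0.0352, adjusted p = 0.462 with an estimated correlation), the 2 being snorc and spp1, an osteopontin gene at a log2 fold change of -3.67 ± 0.53, and the list had an adjusted p of 0.0651 without uncut SB431542 replicate 4. Immediate early genes were higher (1 of 26 called, 5 adjusted over the list alone, list adjusted p = 0.0287, adjusted p = 0.462 with an estimated correlation), the 1 being NR4A1. The aryl hydrocarbon and oxidative stress response was higher with 0 of 21 called (3 adjusted over the list alone, list adjusted p = 0.0287, adjusted p = 0.462 with an estimated correlation), its leading members being the monooxygenase gene cyp1c1 at 1.61 ± 0.35 and the glutathione transferase gene gstp1.2 at 0.90 ± 0.20 on the log2 scale. Circadian clock genes were higher with 0 of 24 called (5 adjusted over the list alone, list adjusted p = 0.0352, adjusted p = 0.552 with an estimated correlation), with tefa at 1.58 ± 0.32 and cry5 at 1.25 ± 0.37. The calls without uncut SB431542 replicate 4 were 1 up and 1 down for cell cycle, 4 of 13 down for bone and cartilage, 4 up for immediate early genes, 3 up for the aryl hydrocarbon and oxidative stress response and 3 up for the circadian clock. The other 28 lists were not called. Among them macrophage markers had an adjusted p of 0.390, neutrophil markers 0.804, fin regeneration genes 0.810, collagens 0.258, TGF-β and activin targets 0.312 and their ligands, receptors and Smads 0.137.

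The count of 40 depended on the fit. It was 473 without uncut SB431542 replicate 4, which is in neither group, and these included all 40. Leaving out 1 of the 6 libraries compared gave 9 to 21 calls, and of the 21 leading genes only UCP2, loxl5b, snorc and SP6 passed in each of these fits. DESeq2 called 323 genes, a fit of only these groups 537, and limma-trend on the deposited normalized values called 14 or 9. The balance of directions also moved, to 6 higher and 8 lower with the replicate number as a block, 3 and 6 on the normalized values with a pseudocount of 0.1, and 2 and 7 without cut DMSO replicate 4.

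SB431542 against DMSO in uncut tails asked what the inhibitor changes without excision. UCP2 was 3.61-fold higher with SB431542 (log2 fold change 1.85 ± 0.25, adjusted p = 0.00801). In all 9 genes were higher and 2 lower. The other leading increases were C11H1orf50 at 3.73-fold, AIFM2, a gene of the defence against lipid peroxidation, at 3.55-fold, the light-responsive gene cry-dash at 3.47-fold, the mitochondrial gene hax1 at 3.32-fold, ucp3 at 3.12-fold and GLRX5, of iron-sulphur cluster assembly, at 36.2 ± 8.73 against 15.8 ± 1.62 CPM, each at an adjusted p of 0.0498. The matrix gene THBS3 (ENSDARG00000077641) was 2.91-fold lower at 8.14 ± 2.56 against 23.4 ± 4.23 CPM (adjusted p = 0.0498).

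Proteases of matrix turnover were higher as a group in uncut tails with SB431542, with 0 of 21 called (6 adjusted over the list alone, list adjusted p = 0.00764, adjusted p = 0.294 with an estimated correlation). Their leading members were MMP9 at 1.79 ± 0.47, HTRA1 (ENSDARG00000032831) at 1.26 ± 0.36, SERPINE2 at 1.14 ± 0.32 and MMP14 (ENSDARG00000008388) at 0.93 ± 0.24 on the log2 scale. None were called over the list alone without uncut SB431542 replicate 4. The aryl hydrocarbon and oxidative stress response was higher, with 0 of 21 called (3 adjusted over the list alone, list adjusted p = 0.0117, adjusted p = 0.289 with an estimated correlation), with gstp1.2 at 0.93 ± 0.20, GSR at 0.85 ± 0.22 and fthl31 at 0.76 ± 0.25. The other 31 lists were not called. The cell cycle list had an adjusted p of 0.370 and a median of 0.03, and without uncut SB431542 replicate 4, whose cell cycle genes were high, it was lower at an adjusted p of 4.74e-07 (adjusted p = 0.507 with an estimated correlation).

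The calls in uncut tails were few and unstable. None of the 8 leading genes passed in every leave-out of 1 library, and edgeR gave 0 calls without uncut DMSO replicate 1, with 2099 genes at an unadjusted p under 0.05, 0 without replicate 2 with 1764, and 0 without replicate 4 with 1844. It gave 1 call without uncut SB431542 replicate 2, 4 without replicate 4 and 666 without replicate 3. Replicate 4 was 1 of 2 libraries left both without replicate 2 and without replicate 3. DESeq2 called 295 genes and limma-voom 1, which was UCP2.

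Across genes, the log2 fold changes of SB431542 in uncut and in cut tails had a Pearson correlation of 0.387 and a Spearman correlation of 0.385. Of the 40 genes called in cut tails, 37 had the same sign in uncut tails. 2 genes were higher in both, where independent lists would share 0.0161, and they were UCP2 and GLRX5.

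Among the genes fixed beforehand as responsive to TGF-β, SMAD7, an inhibitory Smad gene (ENSDARG00000016858), had log2 fold changes of -0.27 ± 0.24 for excision under DMSO and 0.22 ± 0.24 for SB431542 in cut tails, with no call in any comparison. TGFBI (ENSDARG00000071586) stood at 372 ± 45.3 and 300.2 ± 14.9 CPM in cut tails and at 487 ± 32.1 and 432 ± 36.4 CPM in uncut tails, also with no call. The interaction had an adjusted p of 0.910 for SMAD7 and 0.938 for TGFBI. SKIL, skilb and PMEPA1 had 4, 2 and 0 counts over the 12 libraries and were below the filter, so changes in them could not be tested. The reason for the low counts was not examined.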

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

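The tests on recovered reads, limma-voom with library weights, the leave-outs of 1 library for the lists and the correlations, and those of uncut SB431542 replicate 4 where it is in neither group were chosen only after the results had been seen, and the other alternatives were set beforehand. The named genes kept their direction in every alternative and leave-out. Outside the leave-outs they kept their side of the threshold in 2168 cases, lost a call in 149 and gained one in 54, and in the leave-outs the counts were 977, 218 and 11. The lists kept their call in 129 cases, lost it in 41 and gained one in 8, and without uncut SB431542 replicate 4 the counts were 30, 4 and 3. The recovered reads equalled the rounded counts, so their fit repeats the main fit and had to give the same calls. Its cases are among the 2168 kept and add no support.

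Cut against uncut tails under DMSO gave 780 calls, 1468 with only the 2 groups compared and 1642 with library weights. Under SB431542 excision gave 288 calls, 546 with DESeq2 and 127 with only the 2 groups compared. SB431542 in cut tails gave 40 calls, 323 with DESeq2, 130 with no count filter, 14 and 9 on the deposited normalized values with pseudocounts of 1 and 0.1, 14 with the replicate number as a block, 537 with only the 2 groups compared and 636 with library weights. SB431542 in uncut tails gave 11 calls, 1 with RLE, 1 with upper-quartile factors, 295 with DESeq2, 1 with limma-voom, 109 with no count filter, 1 with the stricter filter, 2 and 2 on the normalized values, 18 with the block, 4 with only the 2 groups compared and 2 with library weights. Higher genes made up 81.8% of these 11 calls and 100% of the 1 call with RLE or upper-quartile factors. Their share was 80.7% with DESeq2, 50% with library weights and on the normalized values, and 25% with only the 2 groups compared. The fits did not always call the same genes. In uncut tails all 11 were among the DESeq2 calls, but the block shared 3 of them and the fit of only the 2 groups 1. In cut tails all 40 were called with only the 2 groups compared, but DESeq2 shared 30 of them and the block 10. The causes of these differences between fits were not tested, apart from 1 test for SB431542 in cut tails given below.

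The interaction gave 0 calls, and 1 on the normalized values with a pseudocount of 0.1. That gene, ENSDARG00000110075, is named here after its values were seen. It had 0 CPM in all 3 uncut SB431542 libraries, so its fitted fold is no bound, against 2.99 ± 1.81 CPM in uncut tails with DMSO, and its adjusted p with edgeR was 0.910. The correlation across genes of the excision responses was 0.429, and 0.618 at a mean CPM of at least 5. That of the SB431542 effects was 0.387, 0.527 at a mean CPM of at least 5 and 0.494 with the block.

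Leaving out 1 of the 6 libraries compared gave 321 to 638 calls for excision under DMSO, 119 to 399 under SB431542, 9 to 21 for SB431542 in cut tails and 0 to 666 in uncut tails. Leaving out 1 of all 12 gave 0 to 0 for the interaction and correlations of 0.290 to 0.487 and 0.244 to 0.437. A replicate number is shared between groups. Deviations from the group means of libraries with the same number correlated at -0.0498 to 0.343, the highest being replicate 4 of uncut and cut SB431542 tails. Of 12 libraries, 5 correlated best with their own number. How many would do so by chance was not computed, so whether the numbers mark pairs stays open. The main fit did not use them, and as a block they took SB431542 in cut tails from 40 calls to 14. With 3 libraries a group, edgeR recovered 36% of simulated 2-fold changes, so smaller responses are largely missed.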

Other observations

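The averaged contrast of this part, its genes and lists, and the tests of the outlying library, of muscle RNA and of the spread were chosen only after results had been seen, while the splits of the 5 comparisons and the Hox test were set beforehand. Bounds of 2 predictions, on a cut library under an uncut label and on cell-type makeup, were rewritten after their values had been seen.

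SB431542 averaged over cut and uncut tails raised 677 genes and lowered 326, with 6 libraries per treatment. UCP2 rose by 1.83 ± 0.17 on the log2 scale, from 30.8 ± 11.9 to 109 ± 29.7 CPM (adjusted p = 3.58e-05). EEF2K, the kinase of an elongation factor, rose by 2.78 ± 0.51 (adjusted p = 0.0181), and tefa, a clock-controlled transcription factor gene, by 1.61 ± 0.23 (adjusted p = 0.00338). THBS3 fell by 1.40 ± 0.20 (adjusted p = 0.00187), the DNA ligase gene LIG1 by 0.87 ± 0.16 (adjusted p = 0.00695) and UHRF1, a maintenance gene of DNA methylation, by 0.82 ± 0.18 (adjusted p = 0.0126). The aryl hydrocarbon and oxidative stress response was higher, with 4 of 21 genes up and 0 down (8 and 1 adjusted over the list alone, list adjusted p = 0.00560, adjusted p = 0.167 with an estimated correlation), among them cyp1c1 by 1.28 ± 0.26 and gstp1.2 by 0.91 ± 0.14.

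Proteases of matrix turnover were higher on average, with 4 of 21 genes up (8 adjusted over the list alone, list adjusted p = 0.0234, adjusted p = 0.361 with an estimated correlation), among them MMP9 by 1.54 ± 0.26. Cytokine genes were higher with 5 of 23 up (6 adjusted over the list alone, list adjusted p = 0.0470, adjusted p = 0.361 with an estimated correlation). Immediate early genes were higher with 4 of 26 up (10 up and 2 down adjusted over the list alone, list adjusted p = 0.0441, adjusted p = 0.456 with an estimated correlation). When uncut SB431542 replicate 4 was left out, cytokine and immediate early genes lost their call, with list adjusted p-values of 0.0619 and 0.0515. Proteases kept theirs at 0.0111. Cell cycle genes were then lower at 1.59e-05 and bone and cartilage genes at 0.0260 (0.617 and 0.293 with an estimated correlation). Leaving out 1 library gave 317 to 1664 calls. Only 1 of the 40 splits of the libraries, the real one, gave as many as 1003, the highest other giving 2. The other splits were drawn at random, and the contrast was chosen after results had been seen. Chance is thus made unlikely for these libraries but is not excluded. Replicate number 1 occurred only under DMSO, while both SB431542 groups held numbers 2, 3 and 4. If the numbers mark clutches, treatment is partly confounded with them, which the splits do not address. With the replicate number as a block 884 genes were called, 692 of them among the 1003.

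For the single comparisons the 10 splits are too few for a share under 0.05. The real split was the 1 with as many calls for excision under DMSO (780, highest other 0), excision under SB431542 (288, highest other 10), SB431542 in cut tails (40, highest other 1) and SB431542 in uncut tails (11, highest other 1). For the interaction the real count was 0, which each of the 40 splits reaches whatever the data, so they say nothing of chance.

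Uncut SB431542 replicate 4 lay apart from the other libraries. On a score of the excision response, 0 for the other uncut and 1 for the cut SB431542 libraries, it lay at 0.285. That was above every other uncut library of either treatment, which lay at -0.142 to 0.00180, and the reason was not tested. The lowest cut SB431542 library lay at 0.829, which argues against a library of cut tails alone under an uncut label. The total count of uncut SB431542 replicate 4, 10.844 M, was inside the range of the others, which argues against low depth. Of 13 cell-type lists, 3 deviated most in this library, and 3 did in another library, so a different makeup of cell types stays open. The design gives no biological explanation to test.

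After excision muscle and neural lists were lower and immune lists higher, which tissue from a more anterior level might also show. The log2 ratio of 6 Hox13 to 9 Hox9 and Hox10 genes was higher in cut tails by 0.757 (exact permutation p = 0.00500, the smallest possible of 400 relabellings), opposite to a more anterior level, although Hox13 genes may themselves respond to excision. The ratio uses summed CPM, of which HOXC13 (ENSDARG00000070353) gave the most, a mean of 22.6. No single Hox13 gene was called (lowest adjusted p = 0.147). All 6 were higher under DMSO, while hoxa13a and hoxd13a had log2 fold changes of -0.03 and -0.30 under SB431542. The prediction for a lower share of muscle RNA alone was that the other cell-type lists lie above 0, since the values are relative. TMM scaling holds most genes near 0, with a median of 0.0186 under DMSO. Such a share could therefore leave those lists near 0, but would not put them below it. Under DMSO the mean of neurons and glia had a 95% upper end of -0.304 over its 36 genes. Genes are not independent replicates, so this interval does not measure the spread between libraries. Between libraries, edgeR called 5 of these genes lower and 0 higher under DMSO, which argues against muscle RNA alone in that comparison. Under SB431542 it called 0 of the 36 in either direction (6 lower and 0 higher adjusted over the list alone). Entry of leukocytes and other changes of makeup were not separated from changes within cells.

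Few genes were called for SB431542 in cut tails, and a hypothesis is that uncut SB431542 replicate 4 widens the spread shared by the groups. Without it 473 genes were called, against 40 with it. Leaving out replicate 2 or 3 of that group gave 153 and 106, and uncut DMSO replicate 1, 2 or 4 gave 17, 20 and 43. A fit of only the 2 cut groups, which uses no uncut library, gave 537 calls. With limma-voom 34 genes were called, and 636 with library weights. Uncut SB431542 replicate 4 had the lowest weight, 0.267, against 0.640 to 1.98 for the other libraries. The count thus depended on the uncut SB431542 libraries in the shared fit. It rose more than 1.5 times when any 1 library of that group was left out, not replicate 4 alone, so the test is undecided on replicate 4 as the only source.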
